A study of Bacillus subtilis subsp. subtilis str. 168 with 2 samples.

How the data were processed

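The series holds 2 RNA-seq libraries of *Bacillus subtilis* 168, 1 treated with DMSO and 1 with berberine and (-)-roemerine. Per the labels' protocols, cultures grew in nutrient broth at 37 °C with shaking at 180 rpm to an OD600 of 0.55 ± 0.05, the compounds acted for 1 h, and RNA was stabilised and column-purified before sequencing. Groups were taken from the sample labels.

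The deposited data are 1 table with 4332 features. Per the submitters' processing notes, the authors used DESeq2 under R 3.3.3, and no version of DESeq2 was stated there. The aligner, read counter, strand setting, genome build and annotation are not given in the sources used here, so reads of near-identical or overlapping genes and of antisense transcripts cannot be told apart, and no coordinates are printed. Per the file headers, the table gives the mean of the normalised counts (a signal pooled over both libraries), a log2 fold change with its standard error, a test statistic (a score, equal to the fold change divided by its error), a p-value and an adjusted p-value. These p-values were deposited by the authors from a fit with 1 library per group, in which the spread could not be estimated from replicates. In 71 features the deposited mean is 0 and the other cells hold a spreadsheet mark for a missing value. The largest deposited fold changes are smaller for features with low means, as a fold change shrunken towards 0 would be. The direction of the contrast is not named in the file. A positive value was read as treated over DMSO from the order in the series' design text, and no value was used to choose that reading.

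The deposited log2 fold change was used for every count of features and for every list median. Because a mean over 2 libraries of counts divided by size factors is a sum of whole multiples of 2 steps, the reads in each library were solved for. All 4261 features with a value (100%) had a solution in whole reads, 2454 of them only 1. Solutions lay within 1.02 times the rounding error of the last digit of the printed mean. For the other 1807, a local fit over 15 features with similar values predicted the unshrunken ratio from the deposited fold change. The solution closest to that prediction was taken. The median difference from the prediction was 4.87e-05 on the log2 scale for the chosen solution (largest 0.257) and 0.93 for the next (smallest 0.0045). The size factors were 1.13 for the treated library and 0.888 for the DMSO library, and the totals were 4428473 and 4806631 reads. Which total belongs to which library depends on the same reading of the direction. On 4253 simulated features with these depths, 200 of them given known fold changes, 100% of the read pairs were recovered at each fold size. The simulated fold changes were a smooth shrinkage of the same ratio that the choice between solutions uses. They therefore do not test that choice on the authors' own fold changes. Folds of single genes in the text are ratios of these reads after the authors' size factors, without shrinkage. Their intervals are exact 95% Clopper-Pearson intervals of the share of reads, given without a label after the first use, and they cover counting error only, since sequenced fragments can be copies of 1 molecule. Where a library had 0 reads, the bound was computed with 3 reads in it.

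With 1 library per group no test of the authors' comparison was possible here and no p-value of another kind was computed. Features with a mean of at least 10 were counted at 2-fold or more in each direction. The 48 gene lists, the threshold and the rule for named genes were fixed before the data were examined. So were the alternatives, apart from those computed on the recovered reads. For each list the median over members, its 95% order-statistic interval and its percentile among 10000 random lists of the same size, matched on the mean in 20 bins, were computed, and percentiles from 97.5 up or 2.5 down were called outside the matched range. In simulated lists of 20 features from the 4032 used in that step, 0 of 50 lists without a shift fell outside and 49 of 50 lists shifted by 1.5 on the log2 scale lay above. Those lists were drawn at random from single features. They do not show how lists of operon neighbours, or lists with smaller shifts, would be placed.

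The rule for named genes took the 12 highest and 12 lowest fold changes at a mean of at least 50 and an adjusted p at or under 0.05, all multidrug transporter and regulator genes past 2-fold, 10 fixed exporter genes, and up to 4 members per list with the largest absolute fold change. No gene met the condition on the adjusted p, so the 12 highest and lowest without it were named, a choice made after the values were seen. Genes are named as in the file. Neighbour order, and gene lengths for a check of background reads, were taken from the RefSeq table of assembly ASM904v1, in which 3573 of the 4332 names (82.5%) were found.

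Alternatives covered other fold thresholds (1.5, 3 and 4), other minimum means (none, 50 and 100), centring, other thresholds of the adjusted p, the mean in place of the median, unmatched lists and 1 value per run of neighbours. Total-count and TMM scaling, pseudocounts of 1, 5 and 10 and unshrunken ratios were computed on the recovered reads. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.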

Results

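RNA was measured in 2 cultures of *Bacillus subtilis* 168, a Gram-positive laboratory strain. One culture received the solvent DMSO. The other received 75 mg/L berberine, a cationic plant alkaloid that multidrug pumps export, together with 25 mg/L (-)-roemerine, an aporphine alkaloid. RNA was taken 1 h after the addition. By its title, the series asks about such alkaloids as blockers of efflux pumps. Each group had 1 library, and neither compound was tested alone, so no difference below has a replicate check and none can be assigned to 1 of the compounds. The treated library held 4428473 gene-assigned reads and the DMSO library 4806631, as recovered from the deposited means. The deposited file does not name the direction of its fold change. A positive value was read as higher in the treated library, after the order of the series' design text, and every direction below rests on that reading.

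Transcripts differed widely between the libraries. Genes for iron uptake, tryptophan and histidine synthesis, general stress and several multidrug transporters were higher in the treated library, and the lists of anaerobic respiration and fermentation, citric acid cycle and antibiotic synthesis genes were lower by their medians. Of 4032 features with a mean normalised count of at least 10, 1195 were 2-fold or more higher in the treated library (29.6%) and 1058 were 2-fold or more lower (26.2%), while 1779 differed by less. Scaling by the total reads in place of the authors' size factors adds 0.46 to every log2 ratio. Higher features made up 53.0% of those past 2-fold in the deposited fold changes and 51.9% in the unshrunken ratios of reads, and 65.5% in the latter under total-count scaling, so directions below are relative to the authors' scaling. In the authors' deposited table, fitted without replicates, no feature of 4261 had an adjusted p-value at or under 0.05. The deposited standard errors of the log2 fold change had a median of 1.46, from a spread that could not be estimated from replicates. The reads alone set narrower limits: the 95% counting interval of the ratio lay wholly beyond 2-fold for 1087 features higher and 1011 features lower in the treated library. Such intervals describe these 2 libraries and cover counting error only. Counts at 2-fold and list medians use the deposited fold changes, which are shrunken towards 0, whereas folds of single genes are unshrunken ratios of reads and so are larger.

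Multidrug transporter genes as a group were higher in the treated library, with *yvqJ*, *yceJ* and *blt* furthest up among the named exporters. The list of 42 measured transporter genes had a median log2 fold change of 0.88 (95% interval of the median 0.46 to 1.25), at percentile 98.7 of random lists matched on expression. Of these genes, 19 were 2-fold or more higher, 3 were 2-fold or more lower and 20 differed by less. The gene *blt* encodes a multidrug exporter of the major facilitator superfamily, and it was 49.0-fold higher in the treated library (95% counting interval 35.4 to 69.7, from 2300 reads against 37). Its neighbours were higher too: *bltD*, which encodes a spermine and spermidine acetyltransferase, was 46.3-fold higher (28.8 to 79.8), and *bltR*, which encodes the transcriptional regulator of *blt*, was 37.0-fold higher (24.3 to 59.3). The related exporter gene *bmr* was 2.47-fold higher (2.14 to 2.86, from 790 reads against 252), and *bmrU* next to it was 22.7-fold higher (10.8 to 57.3). The exporter genes *mdr*, also called *bmr3*, and *yusP*, also called *mdtP*, were 4.05-fold (3.45 to 4.78) and 4.14-fold (3.69 to 4.65) higher.

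Among putative transporters of the same superfamily, *yvqJ* had 1041 reads against 4 (205-fold, 79.8 to 754) and *yceJ* 1533 against 9 (134-fold, 70.5 to 294). The gene *yvmA* was 11.1-fold higher (9.57 to 12.9) and *ydeR* 19.6-fold higher (8.78 to 54.2). The remaining transporter genes past 2-fold on the high side, *yqeW*, *ydfJ*, *yvdS*, *yvkA*, *ytbD*, *ybcL*, *yvdR*, *ycnB*, *yubD*, *yfhI* and *ywoG*, lay between 2.39-fold for *ywoG* and 8.91-fold for *yqeW*. Smaller differences were found for *lmrB*, a lincomycin resistance gene (2.05-fold, 1.64 to 2.59), and for *yheI* and *yheH*, which encode a heterodimeric ABC exporter (2.03-fold, 1.55 to 2.70, and 1.47-fold, 1.22 to 1.78). The gene *lmrA*, which encodes the repressor of *lmrB*, was 3.73-fold higher (2.5 to 5.73), and *mta*, which encodes an activator of *bmr* and *blt*, was 3.19-fold higher (1.89 to 5.69).

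Not every exporter gene was higher. The ABC exporter gene *bmrA* was 1.59-fold lower in the treated library (1.39 to 1.83), and *ykuC* was 2.97-fold lower (2.63 to 3.37). The paired small multidrug resistance genes *ebrA* and *ebrB* were 4.02-fold (1.54 to 12.3) and 2.90-fold (1.5 to 5.89) lower, from only 6 and 14 reads in the treated library. The list of 8 regulators and neighbours had 5 members 2-fold or more higher and none 2-fold lower, and its median of 1.37 stayed inside the matched range at percentile 94.8. In the authors' deposited table *blt* had a log2 fold change of 4.12 with a standard error of 1.60 and an adjusted p of 0.486, and *bmr* had 1.08 with 1.39 and 0.888.

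**Figure D1:**
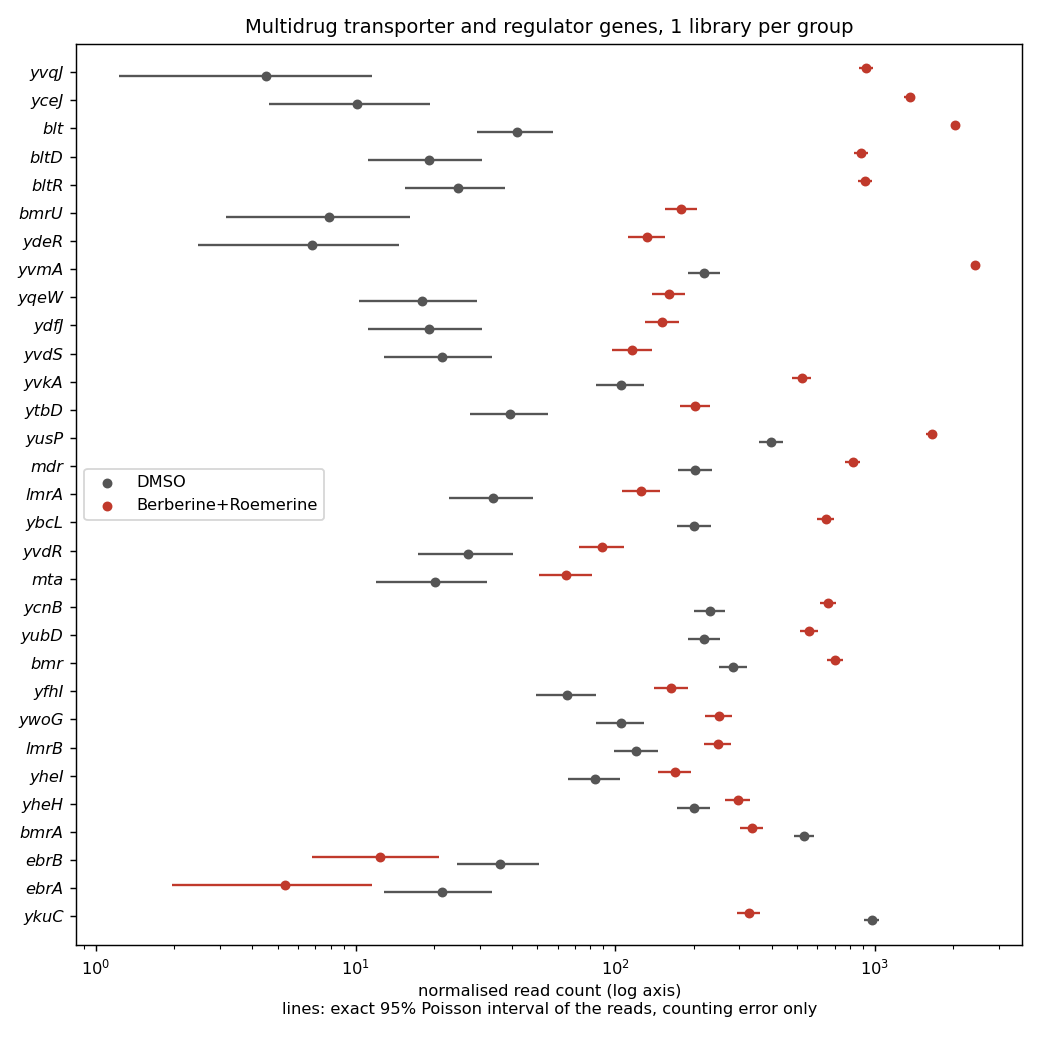
Normalised read counts on a log axis for the multidrug transporter, regulator and neighbouring genes named in the text, with 1 point per library (grey DMSO, red Berberine+Roemerine) and lines for the exact 95% Poisson interval of the reads. The red points lie far to the right for *yvqJ*, *yceJ* and *blt* (205, 134 and 49.0-fold) and to the left of the grey ones for *bmrA*, *ebrA*, *ebrB* and *ykuC*.

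Beyond the exporters, 8 other lists of 48 stood above 97.5% of their matched random lists and 9 stood below 97.5% of them, where 2.4 in all would be expected of random lists. The position is a description of these libraries, since genes are not replicates and neighbours in an operon share their values.

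Iron uptake genes were higher almost throughout. Of 33 measured members of the Fur regulon, the genes that the iron-sensing repressor Fur controls, 28 were 2-fold or more higher and 2 were 2-fold or more lower, with a median log2 fold change of 2.34 (1.85 to 2.96). The genes *feuB* and *feuC*, for uptake of the iron carrier bacillibactin, were 85.8-fold (57.5 to 134) and 80-fold (56.8 to 116) higher. The siderophore-binding protein gene *yxeB* was 72.3-fold higher (41.2 to 140), and *ykuO* had 205 reads against 2.

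Tryptophan and histidine synthesis genes formed the list with the highest median, 2.78 (2.47 to 2.99), with 13 of 15 members 2-fold or more higher. Examples were *trpC* (25.1-fold, 11.3 to 69.2), *trpB* (16.5-fold, 10.4 to 27.6) and *hisG* (18.1-fold, 8.12 to 50.2). The exceptions, named here after their values were seen, were *trpA*, which was lower with a log2 fold change of -1.04, and *hisC*, which was lower at -0.97.

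Stress lists did not all go one way. The SigB, Lia, osmotic and SigW lists had medians above their matched range, whereas the lists for heat shock (5 of 19 members 2-fold higher and 6 lower), SigM (0 of 23 higher and 11 lower) and thiol redox (0 of 7 higher and 5 lower) lay inside theirs. The heat shock member *htrA* was 25.7-fold lower (21.8 to 30.6) and *sigM* itself 5.37-fold lower (4.24 to 6.88). In the SigB general stress regulon, 33 of 59 members were 2-fold or more higher and 5 were 2-fold lower (median 1.21, 0.52 to 1.86), with *ysnF* 45.1-fold (27.2 to 80.9) and *yocK* 42.7-fold (27.2 to 71.2) higher. The gene *yjgB* had 149 reads against 0, at least 39.1-fold higher when 3 reads are allowed in the DMSO library. All 6 members of the Lia cell envelope stress system were 2-fold or more higher (median 1.91, 1.57 to 2.55), among them *liaI* (9.93-fold, 6.49 to 15.9) and *liaH* (6.79-fold, 5.27 to 8.86). Of 23 genes for osmoprotectant and potassium transport, 12 were 2-fold higher and 3 lower (median 1.34, 0.01 to 2.19), with the choline transporter genes *opuBB* (179 reads against 1), *opuBC* (62.9-fold, 26.7 to 195) and *opuBA* (57.7-fold, 24.5 to 179) furthest up. The SigW envelope list had a smaller median of 0.27 (0.07 to 0.64), with 10 of 48 members 2-fold higher and 3 lower. Its members *yaaN* and *yqeZ* were 6.15-fold (5.79 to 6.53) and 5.48-fold (5.19 to 5.79) higher. With 1 value per run of neighbouring genes, the Lia, osmotic, SigW and ribosomal protein lists lay inside the range of random runs, at percentiles of 89.2, 74.5, 77.4 and 89.9. The SigW list also left the top with the mean (94.6) and without matching (81.2), and the osmotic list at a minimum mean of 50 (87.7).

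Early sporulation genes went both ways, with 13 of 25 members 2-fold or more higher and 7 lower (median 1.36, -0.93 to 1.63). The phosphatase gene *spoIIE* was 43.6-fold higher (33.9 to 57.2) and *spoIVFA* 68.3-fold higher (37.0 to 143). That list lost its place with the mean in place of the median, at percentile 88.3, and at a minimum mean of 50, at 95.5. Ribosomal protein genes had a median of 0.85 (0.61 to 0.93), with 16 of 51 members 2-fold higher. Among them *rplJ* was 2.73-fold higher (2.66 to 2.80) and *rpsF* 3.32-fold higher (3.20 to 3.45), while *rpsA* was 14.1-fold lower (13.5 to 14.8) and *rpmF* 2.93-fold lower (2.75 to 3.11).

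Genes for anaerobic respiration and fermentation were lower by their list median, and the nitrate respiration genes among them had some of the largest differences. The operon *narG*, *narH*, *narJ* and *narI*, which encodes the respiratory nitrate reductase, was 63.7-fold (60.1 to 67.6), 77.6-fold (70.4 to 85.8), 83.6-fold (70.6 to 99.7) and 107-fold (94.4 to 123) lower in the treated library. The nitrite exporter gene *narK* was 121-fold lower (104 to 141), the anaerobic regulator gene *fnr* 71.9-fold lower (62.6 to 83.0) and *arfM* 307-fold lower (214 to 459, from 29 reads against 7018). The list of anaerobic respiration and fermentation genes had a median of -2.92 (-4.46 to -0.71), with 14 of 20 members 2-fold lower and 3 higher. The higher members were the nitrate assimilation genes *nasC* (11.5-fold, 6.08 to 24.5) and *nasB* (7.59-fold, 4.72 to 12.9) and the lactate permease gene *lctP* (3.89-fold, 3.78 to 4.01). The lactate dehydrogenase gene *ldh* was 1.11-fold higher (20762 reads against 14789), so genes of lactate fermentation were not among the lower ones. Apart from *nasC*, these were named after their values were seen. In the authors' deposited table *narG* had a log2 fold change of -4.37 with a standard error of 1.60 and an adjusted p of 0.460.

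Citric acid cycle genes were lower nearly throughout. Of 11 members, 10 were 2-fold or more lower and none was 2-fold higher (median -2.43, -2.65 to -1.88). Aconitase *citB* was 10.9-fold lower (10.4 to 11.4), isocitrate dehydrogenase *icd* 10.0-fold lower (9.69 to 10.4) and citrate synthase *citZ* 9.83-fold lower (9.29 to 10.4). In the list of respiratory chain and ATP synthase genes, 21 of 32 members were 2-fold lower and 1 was higher (median -1.20, -1.60 to -0.91), with *cydA* 9.73-fold (9.19 to 10.3) and *atpB* 5.61-fold (5.35 to 5.89) lower. Glycolysis genes stayed inside the matched range at percentile 72.9, with 2 of 17 members 2-fold higher and 4 lower. The 2 higher members were *pdhA* and *pdhB* of pyruvate dehydrogenase. The list's median of -0.32 turns positive under total-count scaling. The list of genes for the use of other carbon sources was lower by its median of -1.05 (-1.41 to 0.13), with 39 of 73 members 2-fold lower and 15 higher. Its members with the largest differences were on the high side, namely *manA* for mannose (62.5-fold, 47.8 to 83.3) and *glpD* for glycerol (57.4-fold, 48.7 to 68.1).

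Manganese uptake genes made up most of the lower members in the list of metal efflux and transport genes, which had 9 of 16 members 2-fold lower and 3 higher (median -1.92, -3.95 to 0.77). The importer gene *mntH* was 46.6-fold lower (43.3 to 50.2), and *mntD*, *mntC* and *mntB* of the manganese ABC transporter were 71.2-fold (59.2 to 86.4), 48.1-fold (41.8 to 55.7) and 39.5-fold (32.3 to 48.8) lower. The gene *zosA*, which is also in the list of the peroxide stress regulon PerR, was 6.48-fold lower (6.09 to 6.89). The efflux and regulator genes of the list went both ways: the higher members, named after their values were seen, were *copA* (log2 fold change 1.75), *arsR* (1.43) and *ydfA* (1.18), while *czcD* (-3.26) and *copB* (-2.74) were lower.

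Antibiotic synthesis genes were lower in 26 of 50 members and higher in 5, both at 2-fold (median -1.14, -1.66 to -0.61). Those furthest down belong to subtilosin production: *albA* was 50.9-fold lower (44.9 to 57.8), *albC* 31.1-fold lower (25.5 to 38.4), and *sboX* had 0 reads in the treated library against 71. Purine synthesis and salvage genes had 12 of 20 members 2-fold lower and 3 higher (median -1.19, -1.52 to -0.70), among them *purF* (4.56-fold lower, 4.09 to 5.09). With 1 value per run of neighbouring genes the purine median was 0.10, so the direction of that list rests on its operon. The purine list also returned inside the range with the mean (3.76) and at a minimum mean of 50 (5.69). The biofilm list, which holds matrix genes and also regulator genes such as *sinR* and *sinI*, had a median of -0.68 (-0.85 to -0.43). Of its 20 members, 4 were 2-fold lower, namely *tasA*, *sinR*, *sinI* and *epsE*, and 1 was higher at all. Genes of the defective prophage PBSX had a median of -0.86 (-1.0 to -0.69), with 8 of 29 members 2-fold lower and 1 higher, and *xre*, the gene of its repressor, was 8.55-fold lower (5.50 to 13.9). With 1 value per run of neighbours PBSX stood at percentile 3.12 and biofilm at 16.5, and biofilm stood at 6.75 without matching.

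The other 30 lists lay inside the matched range. The LexA DNA damage regulon had 4 of 28 members 2-fold higher and 6 lower (percentile 27.8). Of 44 motility and chemotaxis genes 42 differed by less than 2-fold. Cell division genes had 6 of 18 members 2-fold lower and none higher (percentile 51.8). The peroxide stress regulon PerR had 9 of 13 members 2-fold lower, such as *ahpC* (5.51-fold, 5.29 to 5.75), and 1 higher, *mrgA* (22.4-fold, 20.6 to 24.4). Of 18 phosphate starvation genes under PhoP 15 were 2-fold higher (percentile 97.4), whereas *phoP* itself was 10.3-fold lower (7.90 to 13.8).

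**Figure D2:**
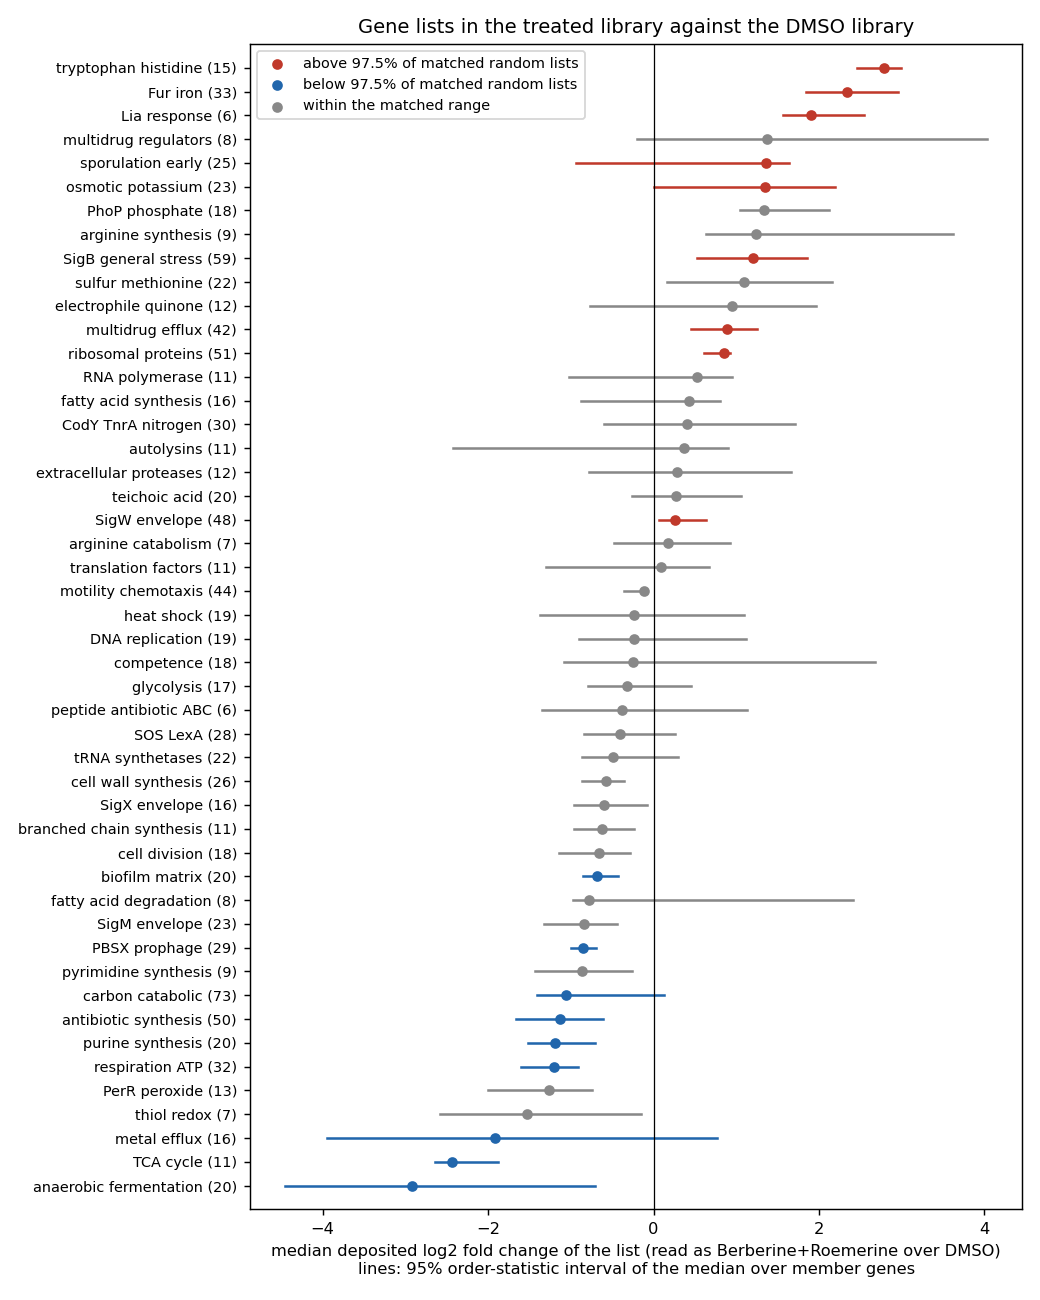
Median deposited log2 fold change of each of the 48 gene lists, with the number of measured members in parentheses and the 95% order-statistic interval of the median over members as a line. Red lists stand above 97.5% of expression-matched random lists, blue lists below 97.5% of them and grey lists between, from tryptophan and histidine synthesis at 2.78 to anaerobic respiration and fermentation at -2.92.

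Outside these lists, the single genes with the highest fold changes at a mean of at least 50 included *frlO* and *frlN* of the fructosamine operon, with 2394 reads against 2 and 1011 against 0, the sulfonate transport genes *ssuA* and *ssuB*, with 569 and 466 reads against 0 in both, and the spore genes *yabG* (2017 against 6) and *sspF* (1039 against 3). When 3 reads are allowed in the DMSO library, *frlN* was at least 265-fold higher, *ssuA* at least 149-fold and *ssuB* at least 122-fold. The set of 12 also held *yonV* (6321 reads against 9), *yjcO* (1942 against 3), *yrkH* (1108 against 2), *ygaK* (3347 against 9), *ytcB* (522 against 1) and *ygzA* (1533 against 0). On the low side, the glycolate oxidase genes *glcD* and *glcF* were 130-fold (105 to 162) and 78.3-fold (64.8 to 95.5) lower, and *ytzE* was 65.2-fold lower (49.5 to 87.5). In the authors' deposited table the highest gene at this minimum mean, *frlO*, had a log2 fold change of 5.60 with a standard error of 1.71 and an adjusted p of 0.442, and the lowest, *arfM* of the anaerobic list, had -5.39 with 1.67 and 0.442.

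The fold change also varied with expression level. In the lowest 2 of 20 expression bins 76.7% and 80.2% of features were higher in the treated library, with median log2 fold changes of 1.05 and 1.24, against 37.8% and a median of -0.66 in the highest bin. The treated library had 43 features with fewer than 3 reads and the DMSO library 298.

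**Figure D3:**
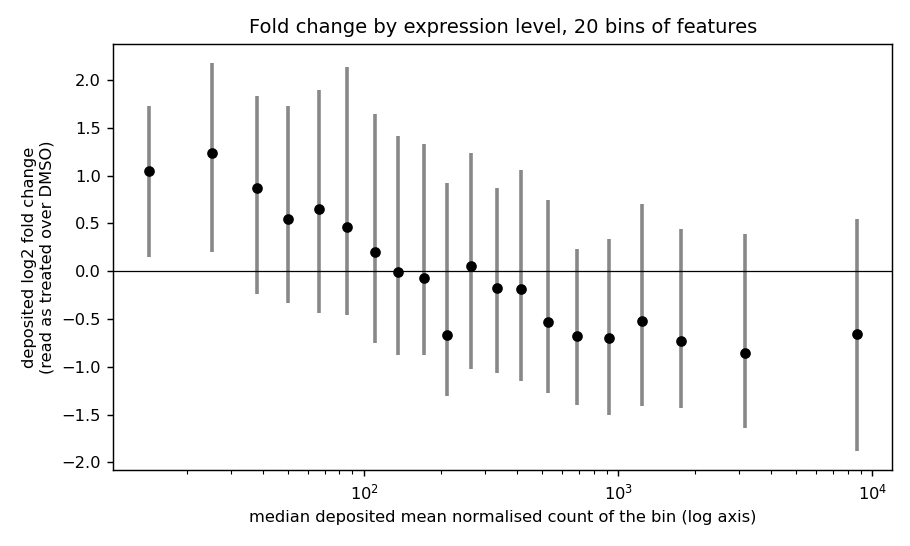
Deposited log2 fold change against the deposited mean normalised count (log axis) in 20 equal bins of the 4032 features, with points for the median and lines for the quartiles of each bin. The median goes from 1.05 in the lowest bin to -0.66 in the highest.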

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

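Unshrunken ratios, total-count and TMM scaling, pseudocounts and the counting-interval count were chosen after the data were seen, because they needed the recovered reads. The number of features past 2-fold stayed within 1.5 times the reported 1195 and 1058 in the other settings, and went beyond that in 4 cases: 677 higher and 282 lower at 4-fold, 502 lower at 3-fold, and 638 higher at a minimum mean of 100, each a stricter threshold. Higher features made up 70.6% of those past 4-fold and 40.7% of those past 2-fold at a minimum mean of 100. The authors' deposited table held 0 features at adjusted p thresholds of 0.01, 0.05 and 0.1. Of the 18 lists outside the matched range, 10 kept their place under all 8 alternatives: multidrug transporters, SigB, Fur and tryptophan and histidine above, and the citric acid cycle, respiration, anaerobic, carbon source, antibiotic and metal lists below. Among these alternatives, centring shifts all values alike and cannot move a percentile. Total-count scaling likewise gave the same percentiles as the unshrunken ratios. With 1 value per run of neighbours, compared with runs not matched on expression, 5 lists stood above, the ribosomal median was 0.49, and the purine median reversed to 0.10. With the mean, tryptophan and histidine came to 2.28 and ribosomal proteins to 0.53, and the SigW, early sporulation and purine lists left their place. Without matching, SigW and biofilm left theirs, and at a minimum mean of 50, early sporulation, osmotic and purine. Further lists entered with the mean, without matching, without a minimum and with runs, such as SigM and thiol redox below. Without shrinkage, medians were 3.70 for tryptophan and histidine, 3.01 for Fur, 1.66 for early sporulation, 1.01 for ribosomal proteins, -0.87 for biofilm, -1.03 for PBSX and -3.04 for the citric acid cycle. Under total-count scaling, which adds 0.46 throughout, they were 4.17, 3.47, 2.13, 1.48, -0.41 and -0.57 for the first 6 of these, 2.83 for Lia, 1.92 for SigB, 1.53 for multidrug transporters and 0.78 for SigW. Other causes of these differences were not tested. No named gene of 230 changed sign under any of the 7 gene-level alternatives, but many had been picked for large fold changes. In 899 of 1610 cases the value moved by more than the gene's counting interval. An edgeR test with an assumed dispersion had been planned only for a file with raw counts and was not run on the recovered reads. No paired analysis was possible because each group had 1 library. At this depth 298 features had fewer than 3 reads in the DMSO library, and their ratios have wide intervals.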

Other observations

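The lists of late sporulation, glycogen, ICEBs1, skin, SPβ, cytochrome bd and cytochrome aa3 genes were chosen after the values were seen. So were the tests of total reads, scaling, glycolysis, the LexA regulon and the background in mobile elements. Genes of late sporulation were mostly higher in the treated library. Of 78 measured genes for coat, germination and small acid-soluble spore proteins and the late sporulation loci, 53 were 2-fold or more higher and 6 lower, with a median log2 fold change of 1.85 (1.36 to 2.40). Its members *spoIVA*, *spoIVFA*, *spoIVFB*, *spoVM* and *spoVG* are also in the early sporulation list, so the early and late lists are not separate. The coat genes *cotSA* and *cotI* had 940 reads against 7 and 1270 against 11, and the germinant receptor gene *gerAA* had 3017 against 37. The 6 lower members were *spoVG* (-2.70), *sspD* (-2.17), *cotD* (-2.15), *sspH* (-2.09), *gerE* (-1.49) and *sspA* (-1.41). Small acid-soluble protein genes went both ways, with *sspF*, *sspG* and *sspC* above 0 and *sspB* and *sspE* below 0 as well. All 5 genes of the glycogen operon were higher, with a median of 4.64 (range of the 5 genes 4.50 to 4.96). Together *glgA*, *glgB*, *glgC*, *glgD* and *glgP* had 12430 reads in the treated library and 100 in the DMSO library. Genes of *B. subtilis* mobile elements were also higher. The integrative element ICEBs1 had 16 of 23 members 2-fold higher and 1 lower, such as *yddH* (164 reads against 0) and *yddE* (1376 against 11), the skin element 36 of 43 and 5, and the prophage SPβ 98 of 141 and 13.

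Features with low counts were mostly higher in the treated library, as reported above for the lowest 2 of 20 expression bins. A deeper treated library would hold more reads in total and have the larger size factor. Its total was 0.921 times that of the DMSO library, but its size factor was 1.27 times the other. The size factor follows the ratios of single features and does not count total reads. These measures point in opposite directions, so they leave depth undecided. An even background of reads, for example from genomic DNA, would give every low feature at least a number of reads in proportion to its length. Of 340 low features with a length (84.2% of 404), 6.76% had an upper counting limit below such a background, and the 95% interval of 4.34% to 9.98% includes the 5% set in advance as the bound. Background therefore remains open, as do depth and an effect of the compounds on genes that are silent during growth. With 1 library per group these cannot be told apart.

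The anaerobic respiration and fermentation list was lower in the treated library, with 14 of 20 members past 2-fold, not including the lactate genes. The scaling of the libraries does not account for it, since the list's median on the recovered reads was -3.74 with the authors' size factors and -3.28 under total-count scaling. A lower central carbon metabolism as a whole would take glycolysis with it, and the citric acid cycle (median -2.43, -2.65 to -1.88) and respiration lists were lower too. The glycolysis list had a median of -0.32 (-0.79 to 0.45) at percentile 72.9 of its matched lists. With 1 value per run of neighbours it stood at 12.7, the lowest of its settings. Its members above 0 were *pdhA*, *pdhB*, *pdhC* and *pdhD* of pyruvate dehydrogenase and the transport gene *ptsG*. Its enzyme genes from *pgi* to *pyk* were all below 0, between -2.01 for *pgi* and -0.10 for *pgm*. The place of this mixed list therefore does not decide the question. A candidate explanation is a different oxygen supply or cell density in the DMSO culture, apart from the compounds. The 4 genes of the operon for cytochrome bd, the oxidase used at low oxygen, had a median of -0.85 against -0.66 in matched lists. They were not alike: *cydA* and *cydB* were at -2.61 and -1.24, and *cydC* and *cydD* at -0.46 and -0.09. The 4 genes for the quinol oxidase cytochrome aa3 were all 2-fold lower with a median of -1.21 against -0.63. These values leave the question undecided. With 1 culture per group a different oxygen supply and an effect of the compounds cannot be told apart.

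The mobile elements ICEBs1, skin and SPβ were higher, with medians of 3.15, 2.93 and 2.05 (4.47, 4.19 and 2.77 for unshrunken ratios with genes at 0 reads set at 3), while the prophage PBSX was lower. The trend of low-count features was smaller than these medians, since lists matched on expression had medians of 0.12, 0.52 and 0.44. Each of the 3 lists stood at percentile 100 of its matched lists. They were chosen after their values were seen, so that place alone excludes nothing. A general DNA damage response would be expected to raise the LexA regulon, which stood at percentile 27.8. Its members went both ways, with 4 of 28 2-fold higher and 6 lower. An even background at the level of the low-count features, 30.4 normalised reads per kb, was exceeded by most of these genes. Of 180 element genes with a length, 66.1% (95% interval 58.7% to 73.0%) had treated counts above their DMSO level plus that background by more than counting error. That interval counts genes as independent, although neighbours in an operon share their values, so it is too narrow. The background level came from features picked for low means and the elements were picked after their values were seen, so the share describes these genes only. An effect of the compounds remains a hypothesis, untested with 1 culture per group.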
